A study of Mus musculus with 4 samples.

How the data were processed

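RNA was extracted with TRIzol from wild-type and Smg6-deficient mouse ES cells, and about 2.5 µg of total RNA per library entered an Illumina TruSeq v2 preparation, which does not mark strand, per the labels' protocols. Single reads of 50 nt were sequenced on a HiSeq instrument, per the labels. Reads were aligned with TopHat2 2.0.9 to mm10, per the submitters' processing notes. The gene counter, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be separated.

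The authors deposited, for each library, a whole-number read count and an RPKM value (read counts scaled by gene length and library size) for each of 37224 Ensembl gene identifiers. Counts were used for the main tests, and the deposited RPKM values for an alternative test and for the ratio of X-linked to autosomal levels. Count totals were 137643993 and 130888768 in the wild-type libraries and 155391181 and 137937779 in the Smg6-deficient libraries. No 2 libraries held identical values, and the replicates of both groups differed by far more than counting noise (chi-square per degree of freedom 74.3 for wild type and 42.0 for Smg6-deficient). Mitochondrial genes took 2.40% and 2.21% of wild-type counts and 1.93% and 2.02% of Smg6-deficient counts. Log2 CPM correlated across genes at 0.993 between wild-type and 0.996 between Smg6-deficient replicates, and at 0.967 to 0.971 between groups, though genes are not independent replicates. No per-sample values of other samples were present.

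Symbols, positions and transcript structures came from GENCODE M21 (GRCm38, the assembly that mm10 names). Of the identifiers, 35449 (95.2%) had a symbol, and 1775 did not. Gene lists held 471 entries, of which 451 matched; 10 of the 20 unmatched entries were noncoding snoRNA hosts.

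Groups were taken from the genotype label. Counts were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F test with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over 20895 genes, with 0.05 as the threshold. Standard errors are the absolute log2 fold change divided by the square root of F. The fit had 2 residual degrees of freedom per gene before moderation and a common biological coefficient of variation of 0.118. The libraries of the groups did not overlap in 73.2% of tested genes, against 33.3% by chance for 2 against 2 libraries. Groups of this size do not allow a test of other splits of the libraries.

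Gene lists and annotated NMD features were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the 20 lists with at least 5 tested members and over the 3 features. Camera was repeated with a correlation estimated from the data, and fry was run. With an estimated correlation, 0 of the 11 lists called by camera passed. The correlations estimated for NMD factors (-0.064) and telomere genes (-0.0047) lay below the preset 0.01, yet their calls were lost too. Correlation between genes therefore does not explain these losses. The fit had 2 residual degrees of freedom, so a lost call does not show that a list did not move. By fry, which tests whether a set moves on balance and compares it with no other genes, 3 of 20 lists passed. The features were a coding transcript with an exon junction over 50 nt after its stop codon, an upstream open reading frame in every coding transcript, and a trailer of at least 2160 nt. The computed leader was followed by ATG in 99.2% of 54127 coding transcripts.

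The gene lists, the tests, the rule for named genes and the alternatives other than those named next as added were fixed before the data were examined. The rule named Smg6; each NMD factor past the threshold; Myc; the 8 largest rises and 8 largest falls with a mean log2 CPM of at least 2 and libraries that did not overlap; and from each list up to 3 members past the threshold with the smallest adjusted p or, where fewer than 2 passed, up to 2 with the highest mean log2 CPM. The values of 1 gene the rule named are not reported here. A list of 23 autosomal germ-cell genes, the restriction to autosomal or coding genes and the correction for length and GC content together were added after the data were seen.

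The alternatives were DESeq2 size factors, upper-quartile factors and library size alone; no filter and a filter of 50 counts in 2 libraries; the DESeq2 1.42.0 Wald test and limma-voom; limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1); the replicate number as a block; a correction for gene length, alone, with the block or with GC content; and leaving out each library in turn. With 1 library left in a group, its spread is assumed to equal that of the other group. The edgeR step was tested on simulated data: counts drawn for 20611 genes in this comparison, with 50 genes changed at each size, gave 23 recovered at 1.5-fold, 44 at 2-fold, 49 at 4-fold and 50 at 8-fold, with 11 false among 177 calls.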

Results

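RNA-seq libraries from mouse embryonic stem (ES) cells of 2 genotypes were compared, with 2 libraries of wild-type cells and 2 of Smg6-deficient cells. Smg6 encodes an endonuclease of nonsense-mediated mRNA decay (NMD), the pathway that degrades transcripts whose stop codon is read as premature. The deposited gene counts summed to 137643993 and 130888768 in wild-type replicates 1 and 2, and to 155391181 and 137937779 in Smg6-deficient replicates 1 and 2. The labels did not say whether libraries of a group came from separate cultures or lines, so the p-values measure only the spread between these libraries, which may be technical. The question the design poses is which transcripts differ in level between cells with and without functional Smg6. Unless stated otherwise, fold changes are Smg6-deficient over wild type, levels are CPM (read counts relative to the TMM-scaled library size) given as mean ± SD (n = 2), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

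Smg6 itself (ENSMUSG00000038290; GRCm38 chromosome 11, 74925823 to 75164448, plus strand, protein coding) was counted at 100.4 ± 6.69 CPM in wild-type and 86.9 ± 0.98 CPM in Smg6-deficient cells. The raw counts were 13396 and 14071 in the wild-type libraries and 13366 and 11642 in the Smg6-deficient libraries. The log2 fold change of -0.21 (SE 0.083) did not pass the threshold (edgeR adjusted p = 0.089). It passed when wild-type replicate 1 was left out (log2 fold change -0.26, edgeR adjusted p = 0.015), when scaled by library size alone (-0.27, 0.044), and with a correction for gene length alone (-0.35, 0.012), with the replicate block (-0.35, 0.0039) or with GC content (-0.37, 0.0094). A count over the whole gene cannot show the loss of some exons, so these values do not check the genotype labels.

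Of 20895 genes tested, 4285 were higher and 4004 lower in Smg6-deficient cells, together 39.7%. At least a 2-fold change was seen for 1133 of the higher and 1678 of the lower genes. The largest rises among genes chosen by the rule included Sox17, Gata6 and Gata4, transcription factors of the endoderm lineage, Cubn, an endocytic receptor of visceral endoderm, Aqp8, a water channel, Dkk1, a secreted Wnt antagonist, and Foxq1, a forkhead factor. Sox17 (chromosome 1, 4490931 to 4497354) rose from 1.27 ± 0.46 to 28.7 ± 12.1 CPM (log2 fold change 4.49, SE 0.37, edgeR adjusted p = 0.00040). Aqp8 rose by a log2 fold change of 5.12, Cubn by 4.95, Dkk1 by 4.07 and Gata6 by 3.98. Foxq1 rose by 3.97 and A530084C06Rik, which overlaps Foxq1 on chromosome 13, by 3.98, so that their reads may be shared. The largest falls were those of 1700013H16Rik (-9.66), 4930550L24Rik (-7.90), Xlr5c (-7.47), Gm9 (-7.07) and Rhox1 (-5.82) on chromosome X, and of Tuba3b (-6.74), 1700018B24Rik (-6.37) and Asz1 (-5.92), a germ-cell gene, on autosomes. Rhox1 (chromosome X, 37213804 to 37222258), a homeobox gene of the Rhox cluster, fell from 34.8 ± 2.39 to 0.61 ± 0.20 CPM (SE 0.22 on the log2 scale, edgeR adjusted p = 8.6e-05). Xlr5c, Tuba3b and the Rhox genes belong to families of similar copies, and their counts are uncertain to that extent. Fewer genes passed when a Smg6-deficient library was left out: 2805 higher and 2336 lower without replicate 1, and 2897 higher and 2300 lower without replicate 2.

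**Figure D1:**
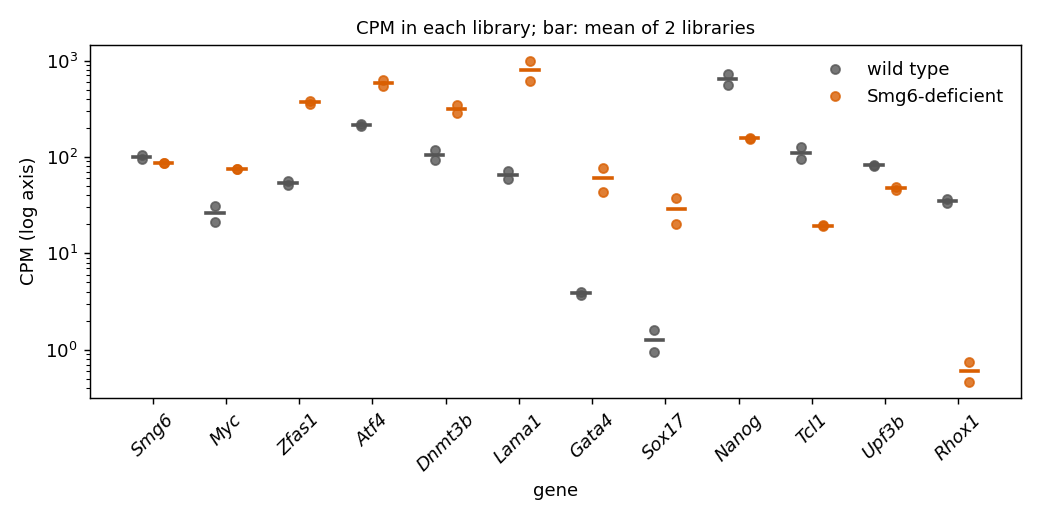
CPM of 12 genes (log axis) in each of the 2 wild-type libraries (grey points) and the 2 Smg6-deficient libraries (orange points), with bars at the group means. Smg6 differed little (100.4 against 86.9 CPM), while Zfas1, Lama1, Gata4 and Sox17 were higher and Nanog, Tcl1, Upf3b and Rhox1 lower in both Smg6-deficient libraries.

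X-linked genes were lower as a whole in the Smg6-deficient libraries. Of 1040 tested X-linked genes, 590 were lower and 37 higher, with a median log2 fold change of -0.76, while the medians of the autosomes lay between -0.017 and 0.107. Among genes with a mean log2 CPM of at least 2, the median RPKM of X-linked genes over that of autosomal genes was 1.32 and 1.28 in the wild-type libraries and 0.70 in both Smg6-deficient libraries. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), fell from 156.1 ± 68.6 to 62.4 ± 6.56 CPM (log2 fold change -1.32, SE 0.27, edgeR adjusted p = 0.0099), and Tsix, transcribed from the opposite strand across it, fell by 1.28 on the log2 scale. The kit did not mark strand, so reads of Xist and Tsix cannot be told apart. The 5 listed Y-linked genes together had 6, 13, 20 and 5 counts in wild-type replicates 1 and 2 and Smg6-deficient replicates 1 and 2. Xist and Tsix were the only members of the list of sex chromosome markers with enough counts to test, so the list had no set test, and both also passed when adjusted over the list alone. Restricted to autosomal genes, a restriction chosen after the X-linked values were seen, 4165 genes were higher and 3326 lower.

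**Figure D2:**
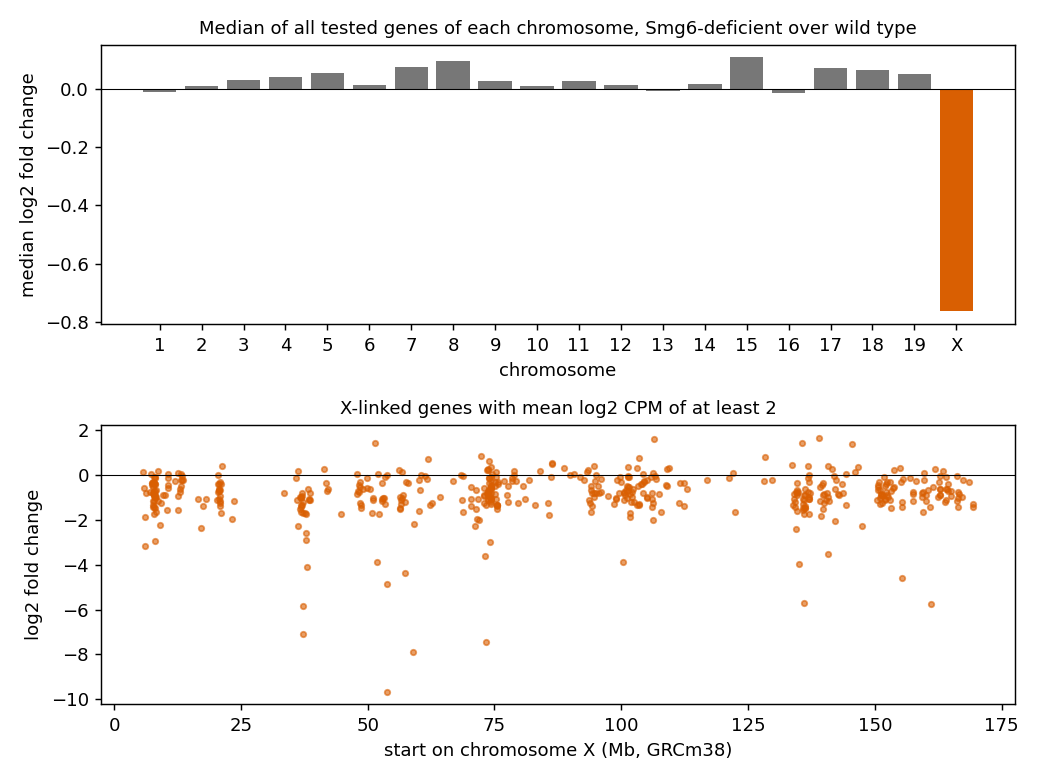
Top, the median log2 fold change (Smg6-deficient over wild type) of all tested genes on each chromosome, with chromosome X in orange. Bottom, the log2 fold change of each X-linked gene with a mean log2 CPM of at least 2 against its start on chromosome X in Mb: the X median was -0.76, the autosome medians lay between -0.017 and 0.107, and lower genes lay along the whole chromosome.

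Factors of the NMD pathway were mostly higher in Smg6-deficient cells. Of 12 tested factors other than Smg6, 9 rose and 2 fell, and the same numbers passed when adjusted over the list alone. Smg9, a regulator of the kinase Smg1, rose from 30.3 ± 3.20 to 60.3 ± 3.06 CPM (log2 fold change 0.99, SE 0.10, edgeR adjusted p = 0.00081). Among the others that rose, Smg1 rose by a log2 fold change of 0.95, Nbas by 0.73, Smg5, an adaptor for decay of phosphorylated Upf1, by 0.72, Dhx34 by 0.57, Pnrc2 by 0.50, Upf2 by 0.41, and the helicase Upf1 by 0.37. Upf3b, the X-linked member, fell by 0.80 on the log2 scale and Smg8 by 0.24, while Upf3a had a log2 fold change of 0.30 that did not pass (edgeR adjusted p = 0.11). The median of the list was 0.45 and camera called it higher (adjusted p = 0.019), but adjusted p = 0.65 with an estimated correlation. That correlation was -0.064, below the preset 0.01, so correlated genes do not explain the loss. The call of Smg8 was lost without either Smg6-deficient library (edgeR adjusted p = 0.35 without replicate 1 and 0.30 without replicate 2). Upf1 (0.18) and Dhx34 (0.056) lost theirs without replicate 1 and Upf2 (0.10) without replicate 2, and Upf1 (log2 fold change 0.11, edgeR adjusted p = 0.29) and Dhx34 (0.27, 0.076) also with the length and GC correction.

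Genes with an annotated NMD-directing transcript were shifted upward. Of 4256 tested genes with a transcript that has an exon junction more than 50 nt after its stop codon, 33.3% were higher and 14.7% lower, against 20.6% and 22.3% of 12208 coding genes without one. Their median log2 fold changes were 0.154 and 0.0036. Camera called the set against all other tested genes (adjusted p = 0.0012, and 0.027 with an estimated correlation). Among coding genes only, a restriction chosen after the data were seen, camera also called it (adjusted p = 0.0065). Upstream open reading frames in the leader of every coding transcript marked 4376 genes, with a median of 0.089 against 0.031 without, and camera did not call this set (adjusted p = 0.32), although it passed with an estimated correlation (adjusted p = 0.027). The 4071 genes with the longest trailers, of at least 2160 nt, had a median of 0.052 against 0.044, and were not called (adjusted p = 0.44).

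Noncoding hosts of small nucleolar RNAs, whose spliced transcripts are known to be NMD substrates, included large rises. Of 10 tested, 5 rose and 2 fell, both over all genes and adjusted over the list alone. Zfas1 (ENSMUSG00000074578; chromosome 2, 167062934 to 167065862) rose from 53.9 ± 3.32 to 369.8 ± 16.7 CPM (log2 fold change 2.78, SE 0.092, edgeR adjusted p = 6.0e-05). Epb41l4aos rose from 20.5 ± 3.54 to 132.8 ± 1.06 CPM (log2 fold change 2.70) and Snhg12 from 39.6 ± 0.39 to 140.8 ± 4.30 CPM (1.83). Gas5, a host often used as an NMD readout, had a log2 fold change of 0.25 that did not pass (edgeR adjusted p = 0.11); it was picked after its value was seen. The list median was 0.41 and camera called it higher (adjusted p = 1.2e-06), but adjusted p = 0.65 with an estimated correlation.

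Coding genes known as NMD targets were divided. Of 20 tested, 7 rose and 3 fell (9 and 3 adjusted over the list alone). Atf4, the transcription factor of the amino acid and stress response, rose from 214.0 ± 6.34 to 588.4 ± 63.7 CPM (log2 fold change 1.46, SE 0.10, edgeR adjusted p = 0.00027), and Gadd45g, a growth arrest gene, rose by 1.24. Rbm3, a cold-inducible RNA-binding protein gene on chromosome X, fell by 1.45 on the log2 scale. Camera did not call the list (median 0.26, adjusted p = 0.15), but it passed on autosomal genes alone (adjusted p = 0.033) and narrowly without Smg6-deficient replicate 1 (adjusted p = 0.04997). Splicing regulators with poison exons, whose inclusion creates NMD substrates, moved one way: 13 of 30 rose and 0 fell, with the same numbers adjusted over the list alone. Luc7l rose by a log2 fold change of 0.86, and the kinases Clk4 and Clk1 rose by 0.65 and 0.50. This list had a median of 0.20 and was called by camera (adjusted p = 0.021), but not without wild-type replicate 2 (adjusted p = 0.082), and adjusted p = 0.65 with an estimated correlation.

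Of 12 exon junction complex and cap-binding genes, 1 rose and 3 fell, over all genes and adjusted over the list alone. Acin1 rose by a log2 fold change of 0.29, and Sap18 and Ncbp2 fell by 0.42 and 0.37 on the log2 scale, and each of these 3 calls was lost when either Smg6-deficient library was left out, with edgeR adjusted p from 0.071 for Sap18 to 0.23 for Acin1. The call of Acin1 also ended with the gene length correction (log2 fold change 0.11, edgeR adjusted p = 0.33) and with the length and GC correction (0.028, 0.80), which ended that of Ncbp2 too (-0.25, 0.076). Of 36 general mRNA decay enzymes, 10 rose and 5 fell (13 and 5 adjusted over the list alone). Skiv2l, the helicase of the Ski complex, rose by 0.86, Pan3, a subunit of a poly(A) nuclease, by 0.66 and the decapping scaffold Edc4 by 0.64. Camera called neither list (adjusted p = 0.47 and 0.19).

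**Figure D3:**
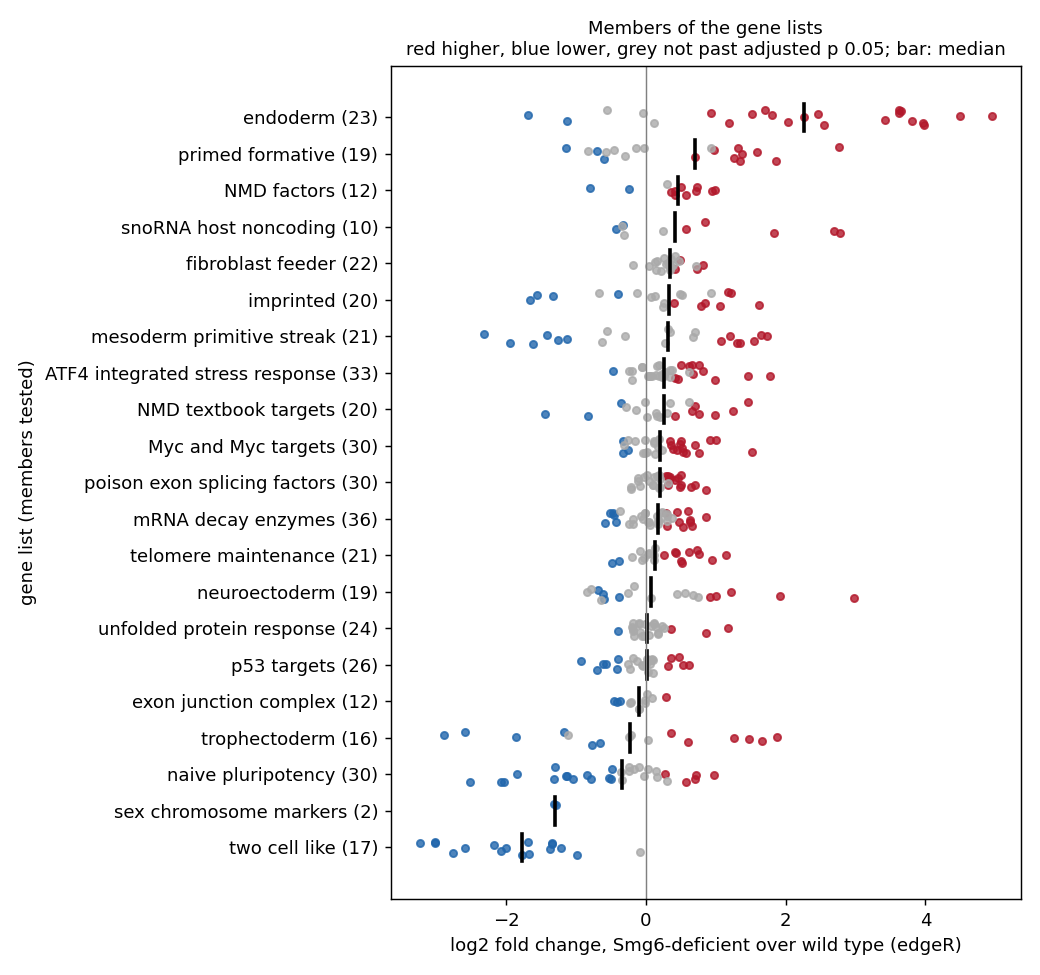
Log2 fold change (Smg6-deficient over wild type, edgeR) of every tested member of 21 gene lists, with 1 point per gene and a black bar at each list's median. Red points passed as higher and blue points as lower at an edgeR adjusted p of 0.05: the endoderm list had the highest median (2.26) and the 2-cell-like list the lowest (-1.77).

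Endoderm genes had the highest median of the 21 lists. Of 23 tested, 18 rose and 2 fell (18 and 3 adjusted over the list alone), with a median log2 fold change of 2.26. Lama1, a laminin chain of the basement membrane, rose from 65.3 ± 8.48 to 804.1 ± 271.4 CPM (log2 fold change 3.62, SE 0.24, edgeR adjusted p = 0.00025), and Gata4 from 3.85 ± 0.21 to 60.3 ± 24.0 CPM. The Smg6-deficient libraries differed from each other here: Cubn stood at 98.6 CPM in replicate 1 and 198.5 CPM in replicate 2, and the median log2 ratio of replicate 2 over replicate 1 over the 18 raised genes was 0.74. Camera called the list (adjusted p = 1.3e-14), but adjusted p = 0.65 with an estimated correlation.

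Genes of naive pluripotency tended to be lower. A difference between lines, such as in X dosage, cannot be told apart from an effect of Smg6 here or for the primed genes below. Of 30 tested, 14 fell and 5 rose (15 and 5 adjusted over the list alone), with a median of -0.35. Nanog, a core pluripotency factor (chromosome 6, 122707489 to 122714633), fell from 640.1 ± 121.0 to 156.1 ± 1.02 CPM (log2 fold change -2.04, SE 0.14, edgeR adjusted p = 0.00025). On the log2 scale, Tcl1 fell by 2.52 and Dppa3 fell by 1.84. Camera called the list lower (adjusted p = 2.7e-05), but adjusted p = 0.65 with an estimated correlation. Of 19 genes of the primed and formative states, 9 rose and 3 fell (10 and 5 adjusted over the list alone), with a median of 0.71. Wnt8a rose by a log2 fold change of 2.76, and the de novo DNA methyltransferases Dnmt3b and Dnmt3a rose by 1.58 and 1.26. Camera called this list (adjusted p = 0.017), but not without wild-type replicate 2 (adjusted p = 0.076) or Smg6-deficient replicate 1 (adjusted p = 0.097), and adjusted p = 0.72 with an estimated correlation.

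Markers of the 2-cell-like state, a rare state of ES cell cultures, were lower in 16 of 17 tested genes, also when adjusted over the list alone. Zfp352 fell by 3.01, Tcstv1 by 2.77 and Tdpoz1 by 3.24 on the log2 scale. Their wild-type levels were 3.91 ± 1.6, 2.06 ± 0.59 and 0.73 ± 0.27 CPM, in that order. The wild-type libraries differed from each other here: Zfp352 stood at 5.04 CPM in replicate 1 and 2.78 CPM in replicate 2. Many of these genes are near-identical copies, so their individual counts are uncertain. Camera called the list (adjusted p = 2.9e-06), but adjusted p = 0.65 with an estimated correlation.

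Other lineages moved in both directions. Of 21 mesoderm genes 7 rose and 6 fell, with Kdr at a log2 fold change of 1.73, Bmp4 at 1.65 and Gata2 at -1.13. Of 19 neuroectoderm genes 5 rose and 4 fell, with Gbx2 at 2.97, Neurod1 at 1.93 and Ncam1 at -0.68. Of 16 trophectoderm genes 6 rose and 6 fell, with the keratins Krt8 and Krt18 at 1.88 and 1.66 and the X-linked Rhox9 at -2.89. The numbers were the same when adjusted over the list alone, and camera called none of these 3 lists (adjusted p = 0.66, 0.47 and 0.73). Fibroblast genes, markers of feeder cells, had 4 of 22 members higher and 0 lower, and 1 higher adjusted over the list alone. Fbn1 rose by 0.73, Timp3 by 0.82 and Col5a2 by 0.41. Timp3 stood at 198.0 and 120.1 CPM in wild-type replicates 1 and 2. Limma-trend on log2(RPKM + 1) called neither Timp3 (log2 fold change 0.78, limma-trend adjusted p = 0.088) nor Col5a2 (0.29, 0.20). The call of Col5a2 was also lost without wild-type replicate 2 (log2 fold change 0.22) or Smg6-deficient replicate 1 (0.39) or 2 (0.45). It was lost too with the gene length correction (log2 fold change 0.24, edgeR adjusted p = 0.22). Camera called this list (median 0.34, adjusted p = 0.028), but not without wild-type replicate 2. The call was also lost with the length and GC correction (camera adjusted p = 0.124) and with an estimated correlation (adjusted p = 0.72).

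Myc (chromosome 15, 61985391 to 61990374), a growth-promoting transcription factor, rose from 26.1 ± 7.28 to 75.1 ± 0.63 CPM (log2 fold change 1.52, SE 0.18, edgeR adjusted p = 0.0012). Of 30 genes in the list of Myc and its targets, 14 rose and 3 fell (14 and 4 adjusted over the list alone), among them Nop56, a ribosomal RNA processing factor (0.92), and Cad, a pyrimidine synthesis enzyme (0.70). Camera called the list (median 0.21, adjusted p = 0.023), but not without wild-type replicate 2 (adjusted p = 0.14), and adjusted p = 0.72 with an estimated correlation. In the integrated stress response, 11 of 33 rose and 1 fell, over all genes and adjusted over the list alone, with the amino acid transporter Slc7a5 at 0.82 and the phosphatase subunit Ppp1r15a at 0.67. The member that fell was the X-linked Slc7a3 (-0.47), chosen after its value was seen. Camera called this list (median 0.26, adjusted p = 0.0049), but adjusted p = 0.71 with an estimated correlation.

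The unfolded protein response had 3 of 24 genes higher and 1 lower, with Herpud1 at a log2 fold change of 1.18, Syvn1 at 0.86 and Hyou1 at 0.36, and the call of Hyou1 was lost without Smg6-deficient replicate 2 (edgeR adjusted p = 0.19) and with the gene length correction (log2 fold change 0.24, edgeR adjusted p = 0.073). Of 26 p53 targets 5 rose and 6 fell, with Aen at 0.61, Pmaip1 at 0.47 and Sesn1 at -0.70; the X-linked Eda2r, chosen after its value was seen, was at -0.93. The p53 list had a median of 0.012 but a mean of -0.065 and a downward direction in camera. The numbers of both lists were the same when adjusted over the list alone, and camera called neither (adjusted p = 0.66 and 0.77). Telomere maintenance genes had 10 of 21 higher and 2 lower, over all genes and adjusted over the list alone. The helicase Rtel1 rose by 1.15, the telomerase-associated Tep1 by 0.94 and the shelterin gene Pot1b by 0.77, while the X-linked Dkc1, chosen after its value was seen, fell by 0.49 on the log2 scale. Camera called this list (median 0.13, adjusted p = 0.028), but not without wild-type replicate 2 (adjusted p = 0.059), and adjusted p = 0.65 with an estimated correlation. Of 20 imprinted genes 7 rose and 4 fell (9 and 4 adjusted over the list alone). Meg3, a maternally expressed noncoding RNA, rose by 1.61 and the paternally expressed Peg3 by 1.18, while Ndn fell by 1.33 on the log2 scale. Camera did not call the list (adjusted p = 0.19). With only genes of at least 50 counts in 2 libraries, camera no longer called the lists of NMD factors (adjusted p = 0.05025) or of poison-exon, Myc, fibroblast and telomere genes (adjusted p = 0.0553 each).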

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

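Tests restricted to autosomal or coding genes and the length and GC correction were chosen after the data were seen. No call turned direction under the alternatives run. Among sets not called in either fit, the camera direction turned for trophectoderm genes (autosomes alone; without wild-type replicate 1), p53 targets (without wild-type replicate 2), the unfolded protein response (without Smg6-deficient replicate 2) and long trailers (length and GC correction). The numbers of genes higher and lower stayed within 1.5 times of 4285 and 4004 under the other scalings, filters and count tests. The rule named genes largely for small adjusted p or large changes in these same libraries. How many of them kept their call therefore does not measure the stability of other genes. Of the 83 named genes besides Smg6, 72 kept their call and direction under all 17 alternatives. The other 11, among them Acin1, Col5a2, Dhx34, Hyou1, Ncbp2, Sap18, Smg8, Timp3, Upf1 and Upf2, each lost their call under at least 1. At least a 2-fold change was met by 1133 and 1678 genes, by construction fewer. Limma-trend called 2700 genes higher on log2(RPKM + 1) and 2643 on log2(RPKM + 0.1); the cause was not tested. Library size alone moved the split to 3761 higher and 4629 lower. Leaving out 1 library gave 2805 to 5578 higher and 2300 to 4899 lower genes; the lowest came from leaving out either Smg6-deficient library, and the cause was not tested.

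With the replicate number as a block, 5074 genes were higher and 4613 lower. The numbers do not establish pairs: same-numbered libraries deviated together with a correlation of 0.155 across genes, from 2 pairs only.

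Smg6 passed the threshold with library size alone (log2 fold change -0.2654), the length correction (-0.3514), the block with the length correction (-0.3509) and the length and GC correction (-0.3714), and ranged from -0.2613 to -0.1589 when 1 library was left out; the cause was not tested.

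With an estimated correlation the 11 called lists had adjusted p of 0.6529 (NMD factors, snoRNA hosts, poison-exon splicing factors, naive pluripotency, endoderm, 2-cell-like, telomere), 0.7119 (stress response) and 0.7243 (Myc, primed, fibroblast), with 2 residual degrees of freedom. By fry, adjusted p was 0.05258 for snoRNA hosts, 0.0562 for poison-exon splicing factors, 0.09866 for the stress response, 0.149 for Myc, 0.08564 for naive pluripotency, 0.1836 for primed, 0.07824 for endoderm, 0.1114 for 2-cell-like and 0.2454 for fibroblast genes, while imprinted genes passed (0.02312). Upstream open reading frames passed with an estimated correlation (0.02651) and by fry (0.003979). The 50-count filter ended the calls of NMD factors (0.05025) and of poison-exon, Myc, fibroblast and telomere genes (0.0553 each), and the length and GC correction that of fibroblast genes (0.124). On autosomes alone NMD targets passed (0.03282). Leaving out 1 library gave adjusted p of 0.003084 to 0.08211 for poison-exon genes, 0.0001093 to 0.1369 for Myc, 2.11e-05 to 0.09734 for primed, 2.855e-06 to 0.2657 for fibroblast, 0.02295 to 0.05918 for telomere genes, 0.04997 to 0.2262 for NMD targets. The cause of these changes was not tested. In the simulation, 23 of 50 changes of 1.5-fold were found. Only 50 genes per size were changed there among 20611, while 39.7% of tested genes passed in the data. The simulated share therefore does not carry over to this comparison, although small changes can be missed.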

Other observations

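Of the tests below, both tests on endoderm genes were chosen after the results were seen, and the germline test after the most changed genes were seen. Germ-cell genes on autosomes were mostly lower in Smg6-deficient cells, in a list of 23 written after the most changed genes were seen. Of these, 17 fell and 2 rose, with a median log2 fold change of -0.84 and quartiles of -1.86 and -0.32. Dazl, an RNA-binding protein of germ cells, fell by 2.03 (SE 0.14), Mael, a factor of transposon silencing, by 2.02 (SE 0.086) and Hormad2, a meiotic chromosome axis gene, by 2.52 (SE 0.18) on the log2 scale, while Tdrd1 (0.64) and Tex14 (0.42) rose; these examples were chosen after their values were seen.

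The fall of X-linked genes (median log2 fold change -0.7628) met the bound set for 1 active X chromosome fewer in the Smg6-deficient cells. The test could have come out the other way. Among X-linked genes with a mean log2 CPM of at least 2, medians of all 10 Mb bins were below 0. They ranged from -1.217 in the bin starting at 30 Mb to -0.1504 in that at 80 Mb. Listed Y-linked genes had few counts in every library. The fall of X-linked genes raises the hypothesis that the lines differ in X dosage, which the design confounds with genotype. The same limit holds for the other shifts between groups, including those of naive, primed and 2-cell-like genes. For the germline genes, the bounds applied to a list written after the most changed genes were seen. X dosage alone was neither met nor excluded for them, because their median (-0.8402) lay between those bounds, and it stays open. An indirect route, for example through DNA methylation, with Dnmt3a and Dnmt3b higher, stays open and untested, as does an effect of Smg6. The fall of the X-linked Upf3b (-0.80) may reflect the line, while that of Rhox1 (-5.82) is larger than 1 X chromosome fewer would give by dose.

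The 18 raised endoderm genes also differed between the Smg6-deficient libraries, by a median log2 ratio of 0.7408 for replicate 2 over 1, beyond that of 10000 random lists matched on expression. This is consistent with a larger share of endoderm-like cells in those cultures, as a hypothesis, but a higher level per cell is not excluded. Feeder fibroblasts stay open as a further source. Camera called fibroblast genes higher (adjusted p = 0.028), but not with an estimated correlation (adjusted p = 0.72) or the length and GC correction (adjusted p = 0.124). Their median was 0.3446 against 2.26 for endoderm genes, but Col1a1 stood at 388.4 ± 89.4 CPM in wild-type cells. Such a baseline would hide a small added share. Whether genotype or line sets the share was not tested.

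Of the 5 raised noncoding snoRNA hosts, 4 overlapped no tested gene on the opposite strand. Znfx1, opposite Zfas1, had a log2 fold change of 0.1224 against 2.78 for Zfas1. Opposite-strand transcripts outside the tested genes were not examined, but reads of tested genes there do not account for the rises. Gene length and GC content do not account for them either: their median log2 fold change was 1.896 after the correction and 1.83 before it, while the correction moved other genes by up to 0.306 (95th percentile). Slower decay of spliced host transcripts without Smg6 remains a hypothesis, since decay was not measured and a difference between lines stays open. Counts over the whole gene do not separate spliced from unspliced transcripts.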
